A study of Mus musculus with 6 samples.

How the data were processed

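RNA sequencing had been run on artery samples from mice 12 to 16 weeks old, 3 with the genotype label g6pd and 3 with the genotype label wild type, per the labels, and the design text speaks of G6PD-deficient mice. G6PD is glucose-6-phosphate dehydrogenase, the enzyme that starts the pentose phosphate pathway and yields NADPH. Per the labels, total RNA was extracted with a Qiagen miRNEasy kit and sequenced on an Illumina HiSeq instrument. The labels disagree on what was sampled: one names a coronary artery (LAD) and cardiac tissue, one names a bovine heart, and the extraction text names aortas. They also disagree on the comparison group, whose genotype label is wild type while its sample titles, the design text and the gene table name it CYPKO. Whether CYPKO denotes a knockout is not given in the sources used here, and if it does, every value given for the wild-type group would be that of a knockout. The titles of that group also end in _R, those of the other group do not, and all 6 titles hold NX. Any difference that goes with the mark _R cannot be told apart from the genotype. The samples are therefore called artery samples here, the group labelled g6pd is called G6PD-deficient after the design text, and the comparison group is called by its genotype label. The labels call the 3 samples of each group biological replicates.

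Per the submitters' processing notes, STAR 2.4.2a and the mouse build mm10 were used. The read cleaning tool, the gene annotation release, the strand setting and the program that made the gene table are not given in the sources used here. The column names of that table follow the layout of a Cuffdiff gene comparison.

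The deposited gene table held 1 FPKM value per gene and group (fragments mapped to a gene, divided by transcript length and library size), which the authors made for each group of 3 samples, per the file headers. It held no values per sample, so no SD, n or left-out sample could be given for a gene. The same table gave the authors' log2 fold change, test statistic, p-value and q-value for 45786 genes, per the file headers. The authors' p-value equalled the two-sided normal probability of their statistic within 2.8e-06, and their q-value equalled a Benjamini-Hochberg adjustment over the 16339 tested genes within 3.3e-06, both checked on the deposited values. The sign of the deposited statistic was opposite to that of the log2 fold change in all tested genes with FPKM above 0 in both groups, so directions were taken from the FPKM. A second deposited table gave counts of raw, cleaned, uniquely mapped and multiply mapped reads for each library. Those counts were used for depth and mapping shares only.

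The main test was the authors' own, with genes called at q below 0.05. This choice, the gene lists, the rule for naming genes and the alternatives listed first below were fixed before the data were examined. An approximate SE of each log2 fold change was derived as the log2 fold change divided by the deposited statistic, in absolute value, and is called the implied SE. It rests on the authors' model and was not computed from samples. Genes with FPKM of 1 or more in at least 1 group and above 0 in both were taken as expressed, which left 13260 genes. Because their median log2 fold change was not 0, log2 values are given relative to that median unless the deposited scale is named.

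For each of 42 gene lists, the median log2 fold change of the expressed members was placed among the medians of 10000 random lists of the same size matched on mean FPKM in 10 bins. A list counted as outside the range when its percentile lay below 2.5 or above 97.5. Genes are not replicates, so the percentile describes these libraries and is no test across mice. The lists covered the contractile apparatus, cGMP and protein kinase G signalling, synthetic smooth muscle, ion channels, vasoactive receptors, TGF-beta and Notch, extracellular matrix, matrix remodelling, pentose phosphate and NADPH enzymes, glycolysis, fatty acid oxidation, lipogenesis, cholesterol, the respiratory chain, antioxidant genes, NADPH oxidases, cytochrome P450 enzymes, stress and immediate early programmes, interferon, inflammation, clock, cell cycle, hypoxia, markers of other cell types, sex-linked and strain-variable genes, histone and mitochondrial transcripts, and ribosomal proteins. Smooth muscle genes outside the contractile apparatus, and further cardiac and adipocyte genes, were listed only after the data were seen. Benjamini-Hochberg adjustment was also run over the tested members of each list alone. It used the authors' p-values on the deposited scale, where most genes were higher in the G6PD-deficient group, and did not adjust across lists.

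The text names G6pdx, the 12 called genes with the largest rise and the 12 with the largest drop (FPKM of 1 or more in the higher group, above 0 in both, no predicted genes or pseudogenes), the 5 called genes of highest FPKM in each direction, up to 4 members of each list with called members first, and any contractile gene. Nos3, Gucy1a3, Pde5a, Higd1a, Ckmt2, Csrp3, Myl4, Ryr2, Fabp3 and Cox7a1 are list members named outside that rule, chosen after their values were seen, and Ikbkg is named for its overlap with G6pdx.

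Gene types and coordinates came from GENCODE M21 on GRCm38, the assembly that mm10 denotes, to which 98.6% of the table's gene identifiers matched. Coordinates are 1-based. Overlapping and antisense genes cannot be told apart without a stated strand setting, and values of genes with near-identical copies are uncertain.

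The alternatives chosen first were q thresholds of 0.01 and 0.10, an FPKM filter of 1 with re-adjustment, a minimum log2 change of 1, Bonferroni, directions relative to the median gene, pseudocounts of 0.1 and 1 FPKM, other FPKM filters for the lists, unmatched random lists and the mean in place of the median. Leaving out each sample was planned and could not be run on pooled values, and splits of the samples into other groups could not be run either. Added after the data were seen were a statistic centred on the median gene with the implied SE, protein-coding genes only, scaling to equal summed FPKM of protein-coding genes, and removal of a quadratic trend in transcript length and GC. Mapping shares were compared with two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3.

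The steps were tested on simulated data. For the comparison of the 2 groups over 13110 genes, with the implied SEs of the real genes and 200 genes changed, the centred statistic recovered 7.5% of changes of 2 on the log2 scale and 48% of changes of 4. Among genes with an implied SE below 1, it recovered 18.7% and 92.9%. With no change simulated it called 0 genes in 1 draw. Each gene was drawn independently from the implied SE that the test then used. These figures therefore cannot check whether the implied SE holds in the real data. Of 200 simulated lists of 20 genes with no change, 4.5% fell outside the range, and 88% did so when 0.5 was added to every member. Values were permuted among genes of like FPKM there, so list members that vary together were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.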

Results

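Arterial transcriptomes of mice deficient in glucose-6-phosphate dehydrogenase (G6PD) were compared with those of mice with the genotype label wild type, 3 samples each. The title of the series poses the question, which is whether smooth muscle contractile genes are raised when G6PD is deficient. Libraries of the wild-type group held 32321259 to 42553902 raw reads and those of the G6PD-deficient group 42469437 to 46562728. Uniquely mapped reads ranged from 18681775 to 26379930 and from 32664468 to 36317423. Expression was deposited as 1 pooled FPKM per gene and group, so levels below carry no spread between samples. The error given with a log2 fold change is the implied SE, derived from the authors' statistic. Folds are ratios of the deposited FPKM, and relative log2 values are log2 fold changes minus that of the median gene. The comparison group is called wild type after its genotype label, although its titles, the design text and the gene table name it CYPKO, and whether that name denotes a knockout is not given in the sources used here.

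The libraries of the groups differed in how their reads mapped. Of the cleaned reads, 63.8% ± 5.25 (SD, n = 3) mapped to 1 place in the wild-type libraries and 80.5% ± 2.81 (SD, n = 3) in the G6PD-deficient ones. Unmapped reads made up 16.0% ± 5.37 and 4.33% ± 1.43, and reads mapping to several places 20.2% ± 0.676 and 15.2% ± 1.56 (SD, n = 3 each). The groups did not overlap in any of these 3 shares, with an exact permutation p of 0.1 for each, the smallest that 3 against 3 allows, and 0.15 after Benjamini-Hochberg adjustment over 6 measures. Whatever lay behind these shares went with the group, so it cannot be told apart from the genotype.

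**Figure D1:**
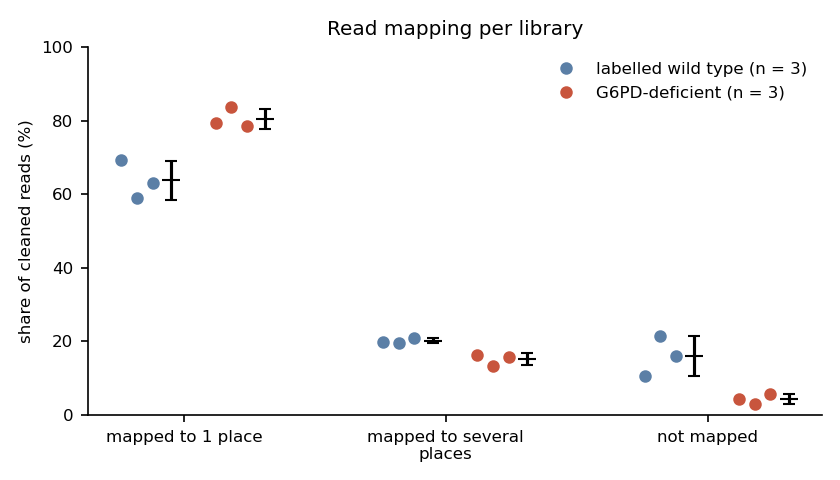
Share of cleaned reads (%) mapped to 1 place, to several places or not at all, per library. Points are libraries, 3 per group, and black bars the mean ± SD. The wild-type libraries lie between 58.9% and 69.4% uniquely mapped, all below the G6PD-deficient libraries at 78.4% to 83.7%.

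The gene of the deficient enzyme had a lower FPKM in the G6PD-deficient group, by a difference within its implied SE. G6pdx (ENSMUSG00000031400.8; GRCm38 chromosome X, 74409483 to 74429194, minus strand) had an FPKM of 7.93 in the wild-type group and 2.61 in the G6PD-deficient group, a 3.03-fold lower level. Its log2 fold change on the deposited scale was -1.60 ± 2.19 (implied SE), and the authors' deposited table gave p = 0.464 and q = 0.999998, so the difference did not pass. Relative to the median gene it was -2.33. The annotation places Ikbkg across the same span, so without a known strand setting its reads cannot be set apart from those of G6pdx.

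Other enzymes that supply NADPH did not pass either. Of 18 expressed genes of the pentose phosphate and NADPH list, 0 were called over all genes and 0 when adjusted over the list alone, with 2 at an unadjusted p below 0.05 in the authors' deposited table. The list had a relative median of -0.30 (percentile 3.56), inside the range of random lists, which was 0.42 on the deposited scale and 0.11 with protein-coding scaling. Malic enzyme 1 (Me1) had an FPKM of 9.35 and 23.1 in the wild-type and G6PD-deficient groups, Me2 1.32 and 3.27, and the mitochondrial transhydrogenase Nnt 4.55 and 11.3.

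Most genes had a higher FPKM in the G6PD-deficient group. This held for 84.1% of the 13260 expressed genes, whose median log2 fold change was 0.73 (1.65-fold). Equalising the summed FPKM of protein-coding genes instead gave a shift of 0.31. Of 16339 tested genes, 317 (1.94%) had q below 0.05 in the authors' deposited table, of which 262 (82.6%) rose and 55 fell. With the statistic centred on the median gene, 149 genes passed, 64 higher and 85 lower (43.0% higher), and 118 of them were among the 317. With protein-coding scaling 196 passed, 136 higher and 60 lower (69.4% higher), 190 of them among the 317.

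The largest rises among annotated genes were those of the olfactory receptor genes Olfr1033 (FPKM 0.187 to 14.8; relative log2 5.58 ± 1.05, implied SE) and its neighbour Olfr1034 (0.0748 to 5.18), whose sequences are related and whose reads may be shared. The bone sialoprotein gene Ibsp went from 0.0343 to 2.11, the glycogen-binding protein gene Stbd1 from 0.912 to 31.5 (relative log2 4.38 ± 0.80) and the prostaglandin transporter gene Slco2a1 from 0.204 to 6.04 (relative log2 4.17 ± 0.81). Mustn1, active in muscle and skeletal tissue, rose from 7.84 to 115.4 (relative log2 3.15 ± 0.59) and Cytl1, a secreted protein of cartilage and vessels, from 6.81 to 94.5 (relative log2 3.07 ± 0.56). Their q in the authors' deposited table was 1.12e-06 for Olfr1033, 1.38e-07 for Stbd1, 9.35e-07 for Slco2a1, 7.03e-08 for Mustn1 and 2.49e-08 for Cytl1. C1s2 (0.0908 to 2.25), AU021092 (0.216 to 4.13), H2-Q1 (0.0666 to 1.33), Cela1 (0.119 to 2.00) and the Wnt inhibitor gene Wif1 (0.130 to 2.08) completed the 12. H2-Q1 has close relatives in the histocompatibility locus, which makes its level uncertain. H2-Q1, Cela1 and Wif1 lost their calls when the statistic was centred, with adjusted p from the authors' statistic of 0.183, 0.180 and 0.0787. The size of rises from near 0 depended on the pseudocount, and with 1 FPKM added the log2 fold change on the deposited scale was 3.74 for Olfr1033, 2.52 for Olfr1034, 1.59 for Ibsp, 2.55 for Slco2a1, 1.57 for C1s2, 2.08 for AU021092, 1.13 for H2-Q1, 1.42 for Cela1 and 1.45 for Wif1.

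The largest drops were led by striated muscle genes. Cardiac actin Actc1 (chromosome 2, 114047282 to 114053548) fell from an FPKM of 19.5 to 0.164, 118.5-fold lower (relative log2 -7.61 ± 1.05), and the myosin light chain gene Myl7 (chromosome 11, 5896637 to 5898782) from 36.8 to 0.572, 64.3-fold lower (relative log2 -6.73 ± 0.95). The cardiac myosin-binding protein gene Mybpc3 fell from 1.56 to 0.0379, its relative Mybphl from 1.53 to 0.0633, cardiac troponin I (Tnni3) from 15.4 to 0.629, the muscle enzyme gene Pgam2 from 2.23 to 0.190 and Eef1a2, an elongation factor of muscle and neurons, from 1.31 to 0.0984. Gdpd3 (11.7 to 0.269), Mroh6 (3.32 to 0.123) and Mettl7a2 (2.13 to 0.0882) also fell. The remaining 2 of the 12 were the non-coding genes Rnu5g, of the spliceosome, and Rprl2, of the ribonuclease P family. The authors' deposited table gave q values of 7.20e-08 for Actc1 and 2.15e-07 for Myl7. All 12 kept their calls when the statistic was centred, a step that makes every drop larger. With 1 FPKM added, the log2 fold change on the deposited scale was -4.14 for Actc1, -4.59 for Myl7, -1.31 for Mybpc3, -1.25 for Mybphl, -3.32 for Gdpd3, -1.94 for Mroh6, -1.52 for Mettl7a2, -1.44 for Pgam2 and -1.07 for Eef1a2.

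**Figure D2:**
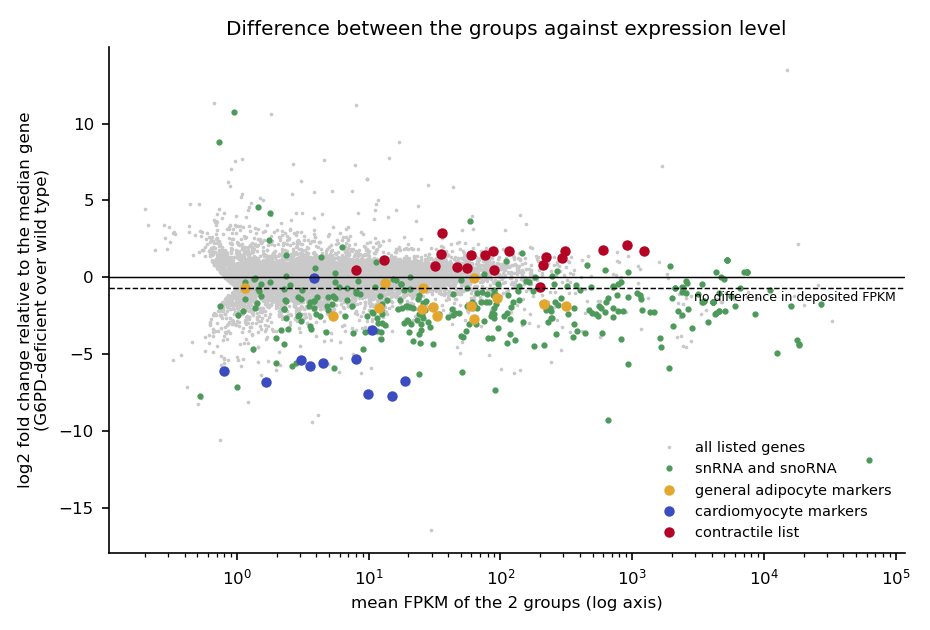
Log2 fold change of the G6PD-deficient over the wild-type group relative to the median gene (vertical axis) against mean FPKM of the 2 groups (horizontal, log axis), 1 grey point per expressed or called gene above 0 in both groups. Coloured points mark the contractile list (relative median 1.38), the cardiomyocyte markers (-5.82), the general adipocyte markers (-1.86) and small nuclear and nucleolar RNAs (-1.87 and -1.88), and the dashed line marks equal deposited FPKM.

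Genes of the smooth muscle contractile apparatus, the subject of the series, were higher in the G6PD-deficient group. All 20 were expressed, 19 lay above the median gene, and the relative median was 1.38 (2.10 on the deposited scale), above all 10000 random lists, whose central range was -0.44 to 0.50. Smooth muscle gamma-actin Actg2 (chromosome 6, 83512905 to 83536265) rose from 5.65 to 66.9, 11.8-fold (relative log2 2.84 ± 0.81), calponin Cnn1 (chromosome 9, 22099216 to 22109630) from 36.3 to 195.8 (5.40-fold, relative log2 1.71 ± 0.73), leiomodin Lmod1 (chromosome 1, 135324807 to 135368065) from 12.2 to 58.0 (4.76-fold, relative log2 1.53 ± 0.67) and Ppp1r14a, an inhibitor of myosin phosphatase (chromosome 7, 29289308 to 29293801), from 21.3 to 97.6 (4.59-fold, relative log2 1.47 ± 0.53). The authors' deposited table gave these 4 genes q values of 0.00178, 0.0445, 0.0460 and 0.00463.

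The other 16 contractile genes did not pass. The count was 4 rising and 0 falling over all genes, and 4 and 0 when adjusted over the list alone. The abundant members were among those that missed, with FPKM of 382.2 and 2057 for Acta2 (relative log2 1.70 ± 1.47), 179.7 and 1020 for Tagln, 225.1 and 1606 for Myl9, and 99.2 and 523 for Myh11. Serum response factor (Srf) had 4.88 and 11.2, its cofactor gene Myocd 17.0 and 47.2, and smoothelin (Smtn) 193.1 and 206.0, a relative log2 fold change of -0.63 that is 0.09 on the deposited scale. With the statistic centred on the median gene none of the 4 passed, with adjusted p of 0.0502 for Actg2, 0.286 for Ppp1r14a, 0.625 for Cnn1 and 0.711 for Lmod1, and with protein-coding scaling Actg2 and Ppp1r14a passed. In the same comparison smooth muscle genes outside the contractile apparatus, listed after the data were seen, had a relative median of 0.70, cardiomyocyte markers of -5.82 and general adipocyte markers of -1.86.

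**Figure D3:**
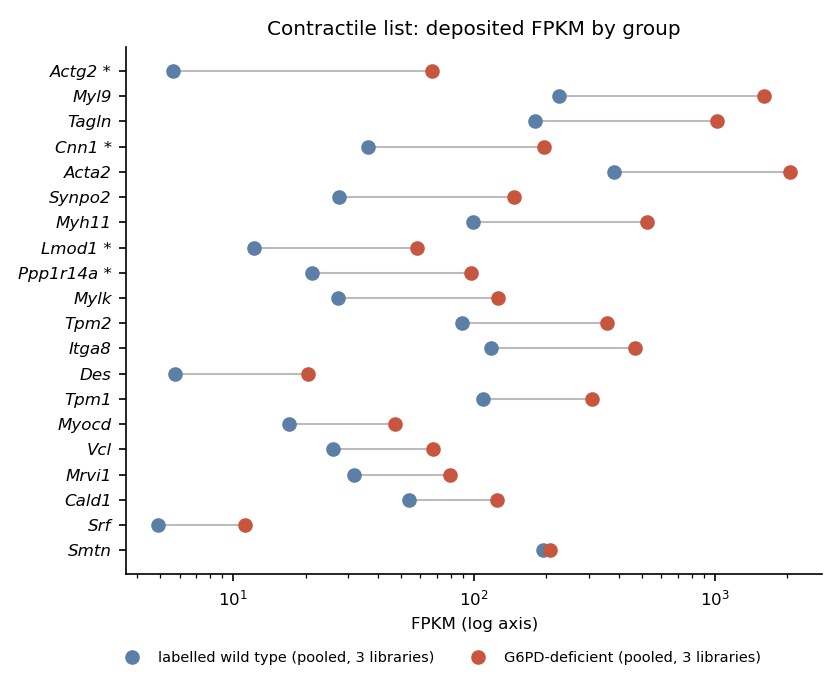
Deposited FPKM (horizontal, log axis) of the 20 contractile genes in the wild-type (blue) and G6PD-deficient (red) group, 1 pooled value per group. Asterisks mark the 4 genes with q below 0.05 in the authors' deposited table, and the smallest fold difference is that of Smtn, at 193.1 and 206.0.

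Genes of cGMP and protein kinase G signalling, through which nitric oxide relaxes smooth muscle, were also higher as a group. Their relative median was 0.62 over 16 expressed genes (percentile 99.9), with 12 above and 4 below the median gene. Phosphodiesterase 3A (Pde3a) rose from 7.04 to 40.6 (relative log2 1.80 ± 0.73), as the 1 gene of the list that passed over all genes, while 3 passed when adjusted over the list alone, namely Pde3a, the myosin phosphatase subunit Ppp1r12a (14.6 and 65.6) and endothelial nitric oxide synthase Nos3. The guanylate cyclase subunit Gucy1b3 stood at 9.05 and 28.8. The call of Pde3a ended when the statistic was centred (adjusted p = 0.507 from the authors' statistic). The smooth muscle genes outside the contractile apparatus, which share Gucy1b3, Gucy1a3 and Pde5a with this list, had a relative median of 0.70.

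Vascular ion channels and calcium handling genes lay inside the range of random lists (18 expressed, relative median 0.22, percentile 86.6), and their relative mean of -0.02 had the other sign. Kcnmb1, a subunit of the calcium-activated potassium channel, rose from 3.75 to 18.6 (relative log2 1.58 ± 0.62) and was the 1 gene that passed over all genes and when adjusted over the list alone. Kcna5 had 1.85 and 0.439 and Trpc3 1.29 and 0.216 without passing. Of 15 expressed vasoactive receptor and enzyme genes, 0 passed by either adjustment, and the relative median was -0.45 (percentile 2.88), with 0.28 on the deposited scale. Ptgis, which makes prostacyclin, had 37.1 and 122.0, Ace 19.0 and 52.4 and Adrb3 8.31 and 2.39. When the statistic was centred, the call of Kcnmb1 ended (adjusted p = 0.422 from the authors' statistic).

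Markers used for synthetic smooth muscle lay inside the range (12 expressed, relative median 0.15, percentile 64.6). The retinol-binding protein gene Rbp1 rose from 6.99 to 26.4 and the transcription factor gene Sox9 from 0.0875 to 0.506, the 2 genes of the list that passed over all genes. Sox9 lay below 1 FPKM in both groups, so it is not among the 12. Matrix Gla protein Mgp (206.6 and 1063) and galectin-3 Lgals3 (1.76 and 7.57) joined Rbp1 and Sox9 among the 4 that passed when adjusted over the list alone. Both calls ended with centring (adjusted p of 0.920 for Rbp1 and 0.607 for Sox9). Extracellular matrix genes (20 expressed, relative median -0.19 and 0.54 on the deposited scale, percentile 14.6) and TGF-beta and Notch genes (19 expressed, 0.21, percentile 85.8) had 0 genes passing by either adjustment. Periostin (Postn) had 43.1 and 204.3, fibulin-5 (Fbln5) 13.9 and 43.2, and the Notch target gene Heyl 15.3 and 60.3. Matrix remodelling genes (14 expressed, 0.29, percentile 89.7, relative mean -0.01) had 0 passing over all genes and 1 when adjusted over the list alone, the protease inhibitor gene Timp4 (15.7 and 3.59), which also passed with the statistic centred (adjusted p = 0.00867 from the authors' statistic).

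Genes of mitochondrial fuel use lay below the median gene. Fatty acid oxidation genes had a relative median of -1.29 over 18 expressed genes (-0.56 on the deposited scale), below all random lists, with 17 of the 18 below the median gene. The fatty acid transporter gene Cd36 had 181.0 and 61.0, the acyl-CoA dehydrogenase gene Acadl 80.8 and 29.7 and Cpt1b 90.4 and 33.9, against 5.94 and 14.8 for Cpt1a. Fatty acid and triglyceride synthesis genes had a relative median of -0.76 over 15 genes (percentile 0.180, and 2.53, inside the range, by the mean), with Acacb at 30.5 and 13.2, the transcription factor gene Mlxipl at 20.03 and 7.005, and Scd1 at 19.9 and 41.6. Nuclear-encoded respiratory chain genes had -0.64 over 19 genes (percentile 1.42, and 4.2, inside the range, among genes with an FPKM of 5 or more), which was 0.09 on the deposited scale and -0.22 with protein-coding scaling. Among them Cox6a2, the form of heart and skeletal muscle, had 2.41 and 0.0143, and Cox8b 184.4 and 112.5. None of these 3 lists had a gene passing over all genes or when adjusted over the list alone, with 1, 0 and 0 genes at an unadjusted p below 0.05 in the authors' deposited table. Cpt1b, Ppargc1a and Fabp3 of the oxidation list and Cox8b and Cox7a1 of the respiratory list also stand among the brown adipocyte markers, whose relative median was -1.35.

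Glycolysis genes (19 expressed, relative median -0.07 and 0.65 on the deposited scale, percentile 26.1) and cholesterol genes (14 expressed, -0.0034 and 0.72 on the deposited scale, percentile 56.1) had 0 genes passing by either adjustment and lay inside the range. The glucose transporter gene Slc2a1 had 2.23 and 8.46, Hk1 5.23 and 12.5, the low-density lipoprotein receptor gene Ldlr 3.27 and 7.78, and Hmgcr, which limits cholesterol synthesis, 2.01 and 3.83.

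Antioxidant genes included some that rose. NAD(P)H quinone dehydrogenase Nqo1 rose from 1.02 to 6.91 (relative log2 2.04 ± 0.59) and Gclc, which limits glutathione synthesis, from 2.10 to 7.38 (relative log2 1.09 ± 0.53), the 2 of 22 expressed genes that passed over all genes. Haem oxygenase Hmox1 (1.23 and 4.13) and extracellular superoxide dismutase Sod3 (25.7 and 104.8) joined them among the 4 that passed when adjusted over the list alone. Neither Hmox1 nor Sod3 passed over all genes with the statistic centred. The relative median of 0.38 lay at the edge of the range of random lists, just inside it. Both calls ended when the statistic was centred (adjusted p of 0.0563 for Nqo1 and 0.985 for Gclc). NADPH oxidase subunit genes (7 expressed, 0.36, percentile 84.4) and cytochrome P450 genes (9 expressed, -0.37 and 0.36 on the deposited scale, percentile 8.59) had 0 genes passing by either adjustment. Nox4 had 27.5 and 67.0, Cyba 6.05 and 21.8, Cyp2e1 17.0 and 6.87 and Cyp4b1 4.33 and 1.35.

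Inflammatory genes were higher as a group, with a relative median of 0.75 over 14 expressed genes (percentile 99.99) and 0 genes passing by either adjustment, against 4 at an unadjusted p below 0.05 in the authors' deposited table. The chemokine genes Ccl8 (0.209 and 2.59) and Cxcl2 (0.113 and 1.62), the adhesion molecule gene Vcam1 (3.13 and 13.4) and P-selectin (Selp, 0.861 and 5.04) led the list. In the same comparison erythroid and platelet markers had a relative median of 0.79 (percentile 99.8) and macrophage markers of 0.34 (percentile 96.7), and platelets also carry P-selectin. Interferon-stimulated genes (10 expressed, 0.01, percentile 60.1), clock genes (17 expressed, -0.08 and 0.65 on the deposited scale, percentile 30.1) and cell cycle genes (4 expressed, 0.16, percentile 72.3) had 0 genes passing by either adjustment. Stat1 had 4.01 and 7.18, Per1 33.6 and 82.3, and Pcna 4.57 and 11.2.

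Stress-response lists lay inside the range with single genes that rose. Of the 19 immediate early genes (relative median 0.27, percentile 85.9), Nr4a1 rose from 20.8 to 97.2 and Egr3 from 0.390 to 2.03, 2 genes both over all genes and when adjusted over the list alone. Of the 15 heat shock genes (0.22, percentile 80.4), the small heat shock protein gene Hspb8 rose from 7.44 to 29.7, and Hspb1 (30.9 and 91.3) joined it as 1 of 2 when adjusted over the list alone. Of 14 expressed hypoxia-inducible genes (0.02, percentile 48.2), the oxygen sensor gene Egln3 rose from 0.625 to 3.21, 1 gene over all genes and 3 when adjusted over the list alone, with Ddit4 (10.2 and 35.0) and Higd1a, while Vegfa had 34.8 and 9.79. Genes of the unfolded protein response (16 expressed, -0.0005 and 0.72 on the deposited scale, percentile 43.3) had 0 passing by either adjustment, with Asns at 5.24 and 1.41 and Calr at 27.6 and 67.7. With the statistic centred the calls of Nr4a1, Egr3, Hspb8 and Egln3 ended, with adjusted p of 0.449, 0.619, 0.807 and 0.312.

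Cardiomyocyte and adipocyte markers lay low in the G6PD-deficient group. Of 17 cardiomyocyte markers 11 were expressed, all of them below the median gene, with a relative median of -5.82 ± 0.91 (median absolute deviation), below all random lists. Actc1, Myl7, Mybpc3 and Tnni3 fell, 4 genes over all genes, and 7 fell when adjusted over the list alone, the others being Ckmt2, Csrp3 and Myl4. The calcium release channel gene Ryr2, which smooth muscle also expresses, had a relative log2 fold change of -0.05 and 0.67 on the deposited scale. General adipocyte markers (14 expressed, -1.86 ± 0.60) and brown adipocyte markers (12 expressed, -1.35 ± 0.55) lay below all random lists, with 0 genes passing by either adjustment. Adiponectin (Adipoq) had 50.8 and 14.6, perilipin (Plin1) 36.4 and 14.6, Lpl 101.3 and 24.8, and Slc27a2 10.9 and 2.08.

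**Figure D4:**
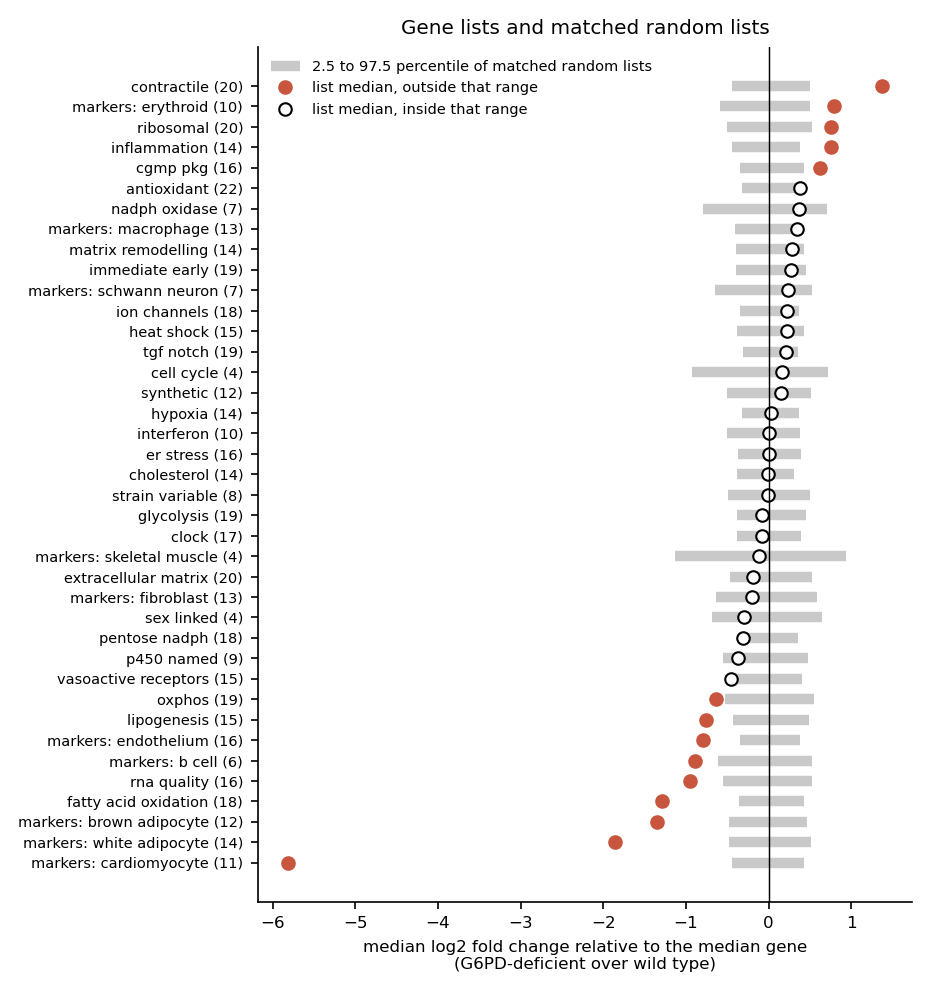
Median log2 fold change of each gene list relative to the median gene (filled red where outside, open where inside the grey central range of 10000 matched random lists), with expressed members in brackets. Of 39 lists with 3 or more expressed genes, 5 lie above and 9 below the range, and the cardiomyocyte markers lie lowest at -5.82. If members varied independently 1.95 lists would lie outside, but genes of a list can vary together and some lists share genes.

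Endothelial markers lay on both sides of the median gene, 4 above and 12 below, with a relative median of -0.80 ± 0.90 (16 expressed, -0.07 on the deposited scale, percentile 0.01), with 0 passing by either adjustment and 3 at an unadjusted p below 0.05 in the authors' deposited table. Pecam1 had 13.001 and 64.5 and von Willebrand factor (Vwf), for which the authors' test failed, 2.60 and 19.96, whereas the growth factor receptor gene Kdr had 10.6 and 1.89 and Robo4 3.18 and 0.501. Robo4 passed with the statistic centred (adjusted p = 0.0314 from the authors' statistic). Erythroid and platelet markers were higher (10 expressed, relative median 0.79, percentile 99.8), with the platelet genes Ppbp (1.26 to 13.2; relative log2 2.66 ± 0.67), Pf4 (4.89 to 28.3) and Gp9 (0.437 to 3.78) rising, 3 over all genes and 3 when adjusted over the list alone. When centred, the calls of Pf4 and Gp9 ended (adjusted p of 0.396 and 0.259) and that of Ppbp held. Macrophage markers (13 expressed, 0.34, percentile 96.7) included Folr2, which rose from 1.39 to 6.46 as the 1 gene passing by either adjustment, a call that centring ended (adjusted p = 0.722 from the authors' statistic), while Cd68 had 1.03 and 4.98.

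B cell markers, which included class II histocompatibility genes, lay below the range (6 expressed, -0.89, percentile 0.460) but inside it by the mean (percentile 5.90) or with no FPKM filter (percentile 19.1), with 0 passing by either adjustment, H2-Eb1 standing at 3.51 and 1.91. Fibroblast markers (13 expressed, -0.20 and 0.53 on the deposited scale, percentile 18.3) and Schwann cell and neuronal markers (7 expressed, 0.23, percentile 82.9) had 0 passing by either adjustment. Gsn had 216.3 and 390.5 and the myelin gene Mpz 0.983 and 5.62. Skeletal muscle markers (4 expressed, -0.12 and 0.61 on the deposited scale, percentile 41.1) had 0 passing over all genes and 2 when adjusted over the list alone, Casq1 (1.56 and 11.9) and Mybpc2 (0.368 and 1.09). No T or NK cell marker was expressed, and 2 neutrophil and mast cell and 2 mesothelial markers were, too few for a median. None of these 3 lists had a gene passing over all genes, and only Upk3b (0.436 and 2.39), a mesothelial marker, passed when adjusted over its list alone.

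Ribosomal protein genes were higher (20 expressed, relative median 0.76, percentile 99.95), with 0 passing over all genes and 3 when adjusted over the list alone, Rps11 (50.9 and 176.1), Rps14 (47.2 and 201.5) and Rpl32 (53.5 and 201.9). Rps21, outside the list and among the most abundant genes that rose, went from 69.5 to 300.4 and lost its call with centring (adjusted p = 0.580 from the authors' statistic). The list of histone and mitochondrial transcripts, set up beforehand as depending on RNA selection, lay below the range (16 expressed, -0.95, percentile 0.180) but inside it by the mean (percentile 13.3). It had 0 genes passing over all genes and 2 when adjusted over the list alone, Hist1h2bc (6.13 and 19.97) and Hist1h4d (51.5 and 155.5). The list did not move as 1 group. Its 4 members above the median gene were the histone genes Hist1h2bc, Hist1h4d, Hist1h1c and Hist1h4i, and the other 12 lay below it. The 13 mitochondrially encoded protein genes had a relative median of -1.34 (-0.62 on the deposited scale), with 0 called.

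Small nuclear RNAs, small nucleolar RNAs and microRNA genes lay lower in the G6PD-deficient group. The 108 expressed small nuclear RNAs had a relative median of -1.87, the 208 small nucleolar RNAs -1.88 and the 76 microRNA genes -1.65, and 10, 2 and 2 of them fell, while 0 of each rose. The 79 expressed genes that the annotation classes as miscellaneous RNA differed from these. Their relative median was -0.30 (0.42 on the deposited scale), and 4 of them rose and 2 fell. The most abundant genes that fell were the small nuclear RNAs Gm22513 (FPKM 124428 to 52.5), Rnu5g (34348 to 2812), Gm25313 (33920 to 2639), Gm25099 (32404 to 3089) and Rnu11 (4882 to 821.4). FPKM of transcripts shorter than a sequenced fragment are unstable, and copies of these RNAs share reads. The most abundant genes that rose besides Rps21 were the miscellaneous RNA genes Gm22701 (13.6 to 3367), Gm26035 (133.1 to 549.2) and Gm24812 (10.2 to 272.1) and the pseudogene Gm15772 (16.2 to 294.7). Of these Gm26035 lost its call with centring (adjusted p = 0.522 from the authors' statistic).

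Y-linked genes were expressed in both groups, Ddx3y at 8.39 and 18.6, Eif2s3y at 12.8 and 16.6, Kdm5d at 3.54 and 4.91 and Uty at 8.81 and 10.6. The sex-linked list lay inside the range (4 expressed, relative median -0.30 and 0.42 on the deposited scale, percentile 15.8) with 0 passing by either adjustment. Strain-variable genes also lay inside the range (8 expressed, -0.01 and 0.71 on the deposited scale, percentile 43.4). H2-Ea-ps, a histocompatibility gene of that list that some inbred strains do not express, was the 1 gene passing over all genes and when adjusted over the list alone. It was listed at 0 in the wild-type group, so it is not among the 8, and at 2.15 in the G6PD-deficient group. Its q in the authors' deposited table was 0.0246.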

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

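The tests of a scale factor, of smooth muscle share, of cardiac and adipose RNA, of a lower smooth muscle share and of chromosomal segments at the pseudogenes were chosen only after the results were seen, as was the search for genes that the authors' test left out. Myh6, Myl2, Myl3, Tcap, Myom1, Xirp1, Myoz2, Pck1 and Aqp7 were named after their values were seen.

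Von Willebrand factor (Vwf), an endothelial gene on chromosome 6 (125546774 to 125686679), had an FPKM of 2.60 in the wild-type group and 19.96 in the G6PD-deficient group, a relative log2 fold change of 2.2135. The authors' test had failed for it, and it was the only 1 of 52 expressed protein-coding genes without a test that differed by 2 or more.

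The contractile genes were higher as a group in the G6PD-deficient libraries. A single scale factor shifts the list and the random lists alike. It cannot by itself place the list 1.3752 above the median gene, outside the range of random lists (-0.44 to 0.50). That follows from the list result itself and adds no independent support. A trend with transcript length and GC did not account for the whole difference. After its removal 1.2394 remained of 1.35, with random lists between -0.20 and 0.47. A larger share of smooth muscle RNA would raise other smooth muscle genes as much only if no other cells expressed them. The 24 such genes had a relative median of 0.6969 ± 0.56 (median absolute deviation) against 1.38. They were chosen as enriched in vascular smooth muscle or pericytes, and expression in other cells would lower their rise. This comparison therefore cannot tell whether share is the whole cause. Those 24 genes themselves lay above all random lists (-0.31 to 0.40), 19 of them above the median gene. Share as part or whole of the cause therefore stays open, as do the genotype and a difference in the tissue taken, which were not tested.

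Cardiac and adipose genes were lower in the G6PD-deficient libraries. A lower share of smooth muscle alone in the wild-type libraries would shift the markers of other cell types alike. The relative medians of the cardiomyocyte, adipocyte, fibroblast and macrophage markers spanned 6.1583, against a largest median absolute deviation of 0.91. This argues against that explanation on its own. The span restates the pattern, since the cardiomyocyte and adipocyte lists are those in which it was seen. More cardiac muscle RNA in the wild-type libraries stays open for the cardiac part. Of 8 expressed cardiac genes outside the marker list 3 lay lower by 2 or more, against 3.70% of all expressed genes. Tcap (14.8 and 59.6, called higher), Myom1 (18.5 and 44.8), Xirp1 (2.99 and 7.23) and Myoz2 (5.40 and 9.28) lay above the median gene instead. Of the 8, 5 had 1 FPKM or more in the G6PD-deficient group, where a source other than heart muscle would hide a drop. Among the abundant cardiac genes Myl7 had 36.8 and 0.572 and Myh6 29.6 and 0.233, while Myl2 and Myl3, abundant in ventricular but not in atrial muscle, lay below 1 FPKM in both groups. More adipose RNA in the wild-type libraries may account for the adipose part, as 14 of 15 expressed adipocyte genes outside the marker list, such as Pck1 (122.5 and 46.8) and Aqp7 (19.8 and 6.96), lay lower by 0.5 or more, against 22.6% of all expressed genes, with 0 of the 15 called, and the genotype stays open.

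Of the 317 called genes, 41 were processed pseudogenes (12.9%, against 5.96% of the tested genes). The 12 called pseudogenes named after a parent differed from it by a median of 2.7215 (0.37 to 6.04). Rps2-ps10, a transcribed processed pseudogene and so not among the 41, had a relative log2 fold change of 5.99 against -0.05 for Rps2. Being called favours a large gap, and a few reads of an abundant parent could move a copy near 0. The comparison therefore cannot exclude reads shared with the parent gene. Rpl27-ps3, Rpl31-ps8, Rpl31-ps9, Rps25-ps1 and Smarce1-ps1 lay within 1 of the parent, and called pseudogenes not named after a parent were not compared with one. Chromosomal segments that differ between the mice stay open, since 6 of the 41 had another called gene within 500 kb, inside the range of 1 to 11 over 2000 random sets of tested pseudogenes, and a strain difference across the genome, with which H2-Ea-ps (listed at 0 and at 2.15) would go, was not tested. These pseudogenes were chosen after their values were seen, and no biological explanation was tested for them.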

How the results depend on the processing

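Scaling to equal protein-coding sums, protein-coding genes only, removal of the length and GC trend, and the centred statistic were chosen only after the results were seen. The contractile list stayed above the random lists under the 6 alternatives that could change its place. Its values there ran from 1.96, which is the list mean, to a median of 2.10 on the deposited scale. It had medians of 1.38 and 1.79 with centring and protein-coding scaling, which shift all genes alike. G6pdx stayed lower, from -1.31 (deposited scale, pseudocount 1) to -2.33 (centred). Leaving out samples and splitting them otherwise were not run, since the values are pooled per group, and a list with fewer than 3 expressed members had no median.

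Of the 317 called genes (262 higher, 55 lower), 177 (136 higher) had q below 0.01 and 79 (59 higher, 20 lower) passed Bonferroni, as stricter thresholds require. With the statistic centred 149 genes passed (64 higher, 85 lower; 118 among the 317), and with protein-coding scaling 196 (136 higher; 190 among the 317). Protein-coding genes alone gave 27 lower genes, since only 28 of the 55 lower genes were protein-coding. Of 200 named genes, 22 lost and 2 gained a call when centred, and 18 lost and 1 gained one with protein-coding scaling. No gene that rose and passed only when adjusted over its list alone passed over all genes with the statistic centred. A pseudocount of 1 moved 38 of the 200 and one of 0.1 moved 10, with 0 changes of sign.

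Centring subtracts 0.73, which by construction turned the sign of Atp5o (-0.071), Cox4i1 (-0.21), Eif2s3y (-0.35), Igkc (-0.30), Kdm5d (-0.26), Mcm3 (-0.35), Smtn (-0.63), Tyms (-0.25) and Uty (-0.46), and protein-coding scaling that of Smtn (-0.21) and Uty (-0.039). It turned the list medians of pentose phosphate (-0.30), glycolysis (-0.074), cholesterol (-0.0034), respiratory chain (-0.64), extracellular matrix (-0.19), unfolded protein response (-0.0005), clock (-0.080), vasoactive (-0.45), P450 (-0.37), fibroblast (-0.20), skeletal muscle (-0.12), sex-linked (-0.30) and strain-variable genes (-0.0123), and protein-coding scaling those of respiratory chain (-0.22) and vasoactive genes (-0.032).

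For the changes that follow, on the deposited scale, the cause was not tested. Removing the length and GC trend placed pentose phosphate (0.34), vasoactive (0.14) and P450 genes (0.24) outside the random lists and turned lipogenesis (0.056) and respiratory chain (-0.054). A pseudocount of 1 placed antioxidant (1.02), vasoactive (0.14), macrophage (0.94) and Schwann cell genes (0.94) outside, and unmatched random lists antioxidant (1.11) and vasoactive genes (0.28). A minimum FPKM of 5 placed NADPH oxidase genes (1.57) outside and respiratory chain genes (0.12) inside, and turned endothelium (0.13). The mean turned respiratory chain (-0.34), placed lipogenesis (-0.075) inside, and both turned and placed inside B cell (0.026) and histone and mitochondrial transcripts (0.16). No filter placed vasoactive genes (0.079) outside, turned skeletal muscle (-0.35) and histone and mitochondrial transcripts (0.27), and both turned and placed inside B cell (0.22).

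Depth per gene is unknown, and the median implied SE of 1.25 limits single genes.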

Other observations

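The genes in this part were chosen only after their values were seen, and no test of them as groups was run.

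Among called genes not described so far, the kinase gene Bmx rose from an FPKM of 0.352 to 4.24, the thrombin receptor gene F2r from 4.69 to 35.3 and the BMP antagonist gene Grem1 from 0.0307 to 0.528, with q values in the authors' deposited table of 5.33e-06, 9.96e-05 and 2.07e-06. These 3 kept their calls when the statistic was centred on the median gene. The connexin gene Gja4 (2.84 to 16.1) and the Wnt inhibitor gene Sost (21.1 to 83.6), with q values of 0.00124 and 0.0487 in the authors' deposited table, did not, with adjusted p from the authors' statistic of 0.109 and 0.896.

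The organic cation transporter genes Slc22a1 (1.49 to 7.99), Slc22a2 (0.210 to 1.60) and Slc22a3 (2.27 to 17.2), neighbours on chromosome 17, had q values in the authors' deposited table of 0.00708, 0.00318 and 1.77e-04. With the statistic centred, only Slc22a3 of these 3 kept its call, with adjusted p from the authors' statistic of 0.268, 0.110 and 0.0248.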
